A study of Drosophila melanogaster with 3 samples.

How the data were processed

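ChIP-seq with an antibody against green fluorescent protein was done on whole embryos aged 0 to 24 hours from flies carrying an Opbp fusion transgene, in 3 biological replicates with 1 technical replicate each, per the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels name a possible control experiment, which was not analysed here.

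The deposited files are peak lists on the dm6 assembly, per the file headers and the labels. Each replicate has a list ranked by the irreproducible discovery rate (IDR), which measures how well peaks repeat between 2 rankings, and a list cut at the authors' IDR threshold. The replicate lists were made for each sample by itself, and 4 further thresholded lists, 1 of them called conservative, cover the series; the latter have no replicate spread of their own. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the authors' deposited value, from the signal column of the list, and was used to describe, rank and filter peaks within a list. Beside the signal, the authors deposited an IDR score and a peak score, and the thresholded lists used here hold IDR scores of 830 or more. The summit is the authors' deposited offset from the peak start. The 4 ranked lists of the series were not used. Some thresholded peaks overlap: merging those that did left 4116 regions from the 4358 conservative peaks, 242 fewer. Overlapping peaks were counted separately.

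Gene models came from Ensembl release 115 and sequence from the RefSeq copy of the same fly assembly; chromosome lengths were checked and all peaks fell within them. The 7 major arms (2L, 2R, 3L, 3R, 4, X and Y) were used, and transposable element genes were left out. A gene was called bound when any of its start sites lay within 500 bp of a summit. Protein-coding start sites within 100 bp on 1 strand were merged into clusters. All tests, gene lists and the rule for named genes were fixed before the data were examined, apart from those said to be added later. The named genes are those at the 25 conservative peaks with the highest signal, Opbp, Optix, and the 4 bound members with the strongest peaks in each list past an adjusted p of 0.05.

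Replicate overlap was counted from 1 bp, and its permutation test drew 1000 placements on the same arm; the tests under other settings drew 200 or 100. For the signal comparison, the ranked-list peak with the highest signal within 100 bp of a conservative summit was taken from each replicate. Shares have exact Clopper-Pearson intervals at 95%, which cover counting error alone. Gene lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, against protein-coding genes for protein lists and all genes for RNA gene lists. For motifs, 8-mers within 50 bp of the summits were compared with 10 control windows per peak, taken at the same offset from unbound start sites. The top 8-mer seeded a matrix of 16 positions, fitted by expectation maximisation, and a match was a score exceeded by 1% of the control windows of the discovery arms. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

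The methods were tested on simulated data. The gene list comparison was simulated 20 times over 18277 genes, with 5 lists bound at 65% among genes bound at 28%. In these runs 97.0% of the planted lists were called, and 0.833% of the tests of other lists. Genes were bound independently there and the shortest lists were not planted, so the rate does not carry over to short lists or weaker excesses. For the motif share, 1 fixed site of 10 bp was planted in 20% of promoter windows. It was found in 191 of the 191 test windows that held it and called in 0.865% of 809 that did not. A site with variable positions was not simulated. For the promoter share, 80% of 3000 simulated summits were planted near start sites. They gave 82.9% where 82.7% was expected, with those that fall there at random counted in. This checks the counting alone.

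The alternatives tried were other windows around the start sites (250 and 1000 bp), other overlap rules, stronger peaks, regions shared by the replicates, a larger thresholded list, other backgrounds and controls, a swap of the discovery arms, and leaving out each replicate in turn. Merged overlapping peaks were added after seeing the data, as were, for the divergent share, the nearest start site alone, a background of start sites near ranked peaks, and the placement of summits at random clusters.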

Results

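Binding of Opbp, a zinc finger protein first described as a partner of the homeodomain protein Optix, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 0 to 24 hours. The flies carried a transgene for Opbp fused to green fluorescent protein, and an antibody against that tag was used for the precipitation. The 3 biological replicates form 1 group, and no second condition was compared. The values here are the authors' peak lists on the dm6 assembly, with the authors' signal for each peak. Replicates 1, 2 and 3 had 2944, 2475 and 3186 peaks past the authors' reproducibility threshold, and the conservative list for all replicates together had 4358 peaks, 4353 of them on the major chromosome arms. Read depth is not given in the peak lists, so the depth behind each signal is unknown.

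The first question was how far the replicates marked the same places. Most peaks of each replicate lay on a peak of another one: 77.9% of the peaks of replicate 1 overlapped a peak of replicate 3 by at least 1 bp, and 72.2% of the peaks of replicate 3 overlapped one of replicate 1. The pairs with replicate 2 ranged from 52.7% to 67.8%. Over the 6 ordered pairs the mean was 65% ± 9.85 (SD over the pairs), against 1.09% for peaks placed at random on the same arm and 15.4% for peaks placed at random promoters. None of the 1000 random placements came above 1.40% (one-sided permutation p = 0.001, the smallest these placements can give). The 3 lists merged into 4327 regions, and 1417 of these, 32.7%, held a peak of every replicate. Across the conservative peaks, the signals of replicates 1 and 3 had a Spearman rho of 0.841 over 3888 matched peaks. Replicate 2 stood further apart, with a rho of 0.611 against replicate 1 and 0.602 against replicate 3. The mean rho of the 3 pairs was 0.684 ± 0.135 (SD, 3 pairs). These are correlations across peaks, which are not independent replicates.

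**Figure D1:**
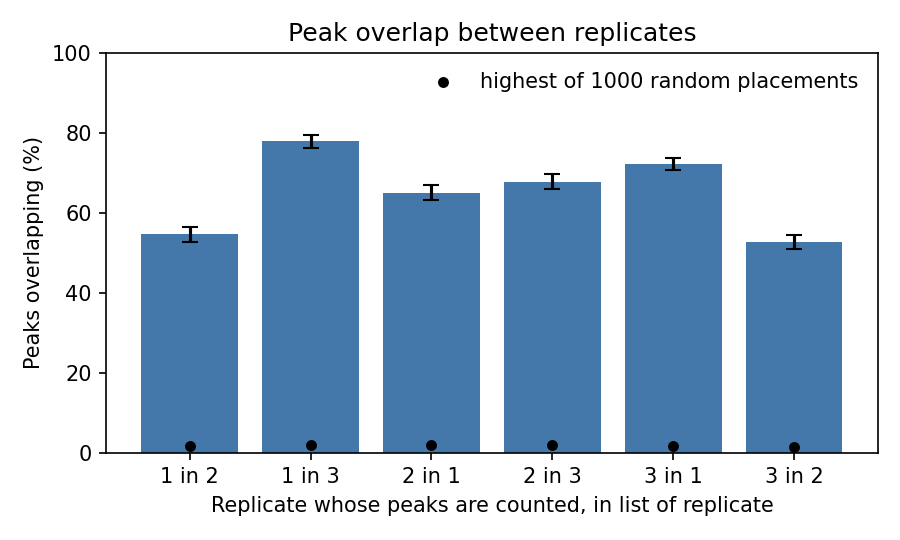
Percent of the peaks of 1 replicate that overlap a peak of another by at least 1 bp, for the 6 ordered pairs, with exact 95% Clopper-Pearson intervals; dots give the highest value of 1000 random placements. The pairs of replicates 1 and 3 stand highest, at 77.9% and 72.2%.

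Opbp-GFP peaks lay at promoters. Of the 4353 conservative summits on the major arms, 3564 were within 500 bp of an annotated transcription start site, which is 81.9% (exact 95% Clopper-Pearson interval 80.7% to 83.0%). The replicates' own lists gave 86.9% ± 1.52 (SD, n = 3), and random placement gave 13.6%, with 15.0% as the highest of 1000 placements (one-sided permutation p = 0.001, the smallest they can give). The median summit was 54 bp from a start site, and 66.2% of the summits were within 100 bp. Among the promoter summits, 65.6% lay upstream of the nearest start site, with a median position of -22 bp. The 5' UTRs held 24.6% of all summits, against 3.22% of randomly placed ones, and intergenic sequence held 46.6% against 30.1%. Introns held 16.7% against 42.4% and coding exons 5.31% against 17.3%. Of the 789 summits farther than 500 bp from a start site, 44.0% were intronic and 32.6% intergenic. Arm 2R had 37.2 peaks per Mb, 2L, 3L, 3R and X had between 31.0 and 32.4, chromosome 4 had 14.8, and no peak was listed on Y.

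**Figure D2:**
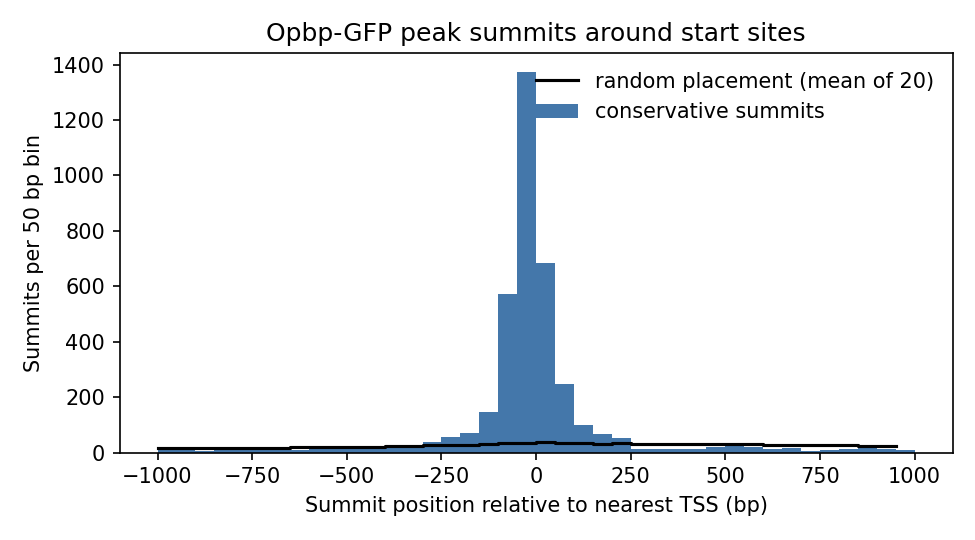
Conservative summits per 50 bp bin by their position relative to the nearest annotated start site, in bp, with upstream negative (bars), and the mean of 20 random placements (line). The summits crowd around a median of -22 bp.

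The 25 peaks with the highest signal all overlapped a thresholded peak in each of the 3 replicates. Of all 4353 conservative peaks 1459 did so, and 843 overlapped a thresholded peak in none of them. The strongest peak, on 3L from 17012387 to 17012778 (all positions are on dm6, counted from 1), had a signal of 3318.7 and a summit 39 bp from the start of CG3764 (FBgn0036684). Its signals in the lists of replicates 1, 2 and 3 were 1247.6, 964.3 and 1115.5. The next, on 2L from 8958293 to 8958591 (signal 3253.9), was 334 bp from a start of CG31886, in an intron. The third, on 2R from 12636471 to 12636850 (signal 2886.2), lay 16 bp from the start of Iswi, which encodes a chromatin remodelling ATPase. The fourth, on 3R from 14890060 to 14890423 (signal 2544.2), lay 7 bp from the start of UQCR-C1, a subunit of respiratory complex III, and 33 bp from that of CycC, a cyclin of the Mediator complex. The fifth, on 3L from 3905171 to 3905506 (signal 2194.7), lay at ida, which encodes a subunit of the anaphase promoting complex. The sixth, on 2L from 5052573 to 5052948 (signal 2175.6), was shared by eIF3h and senju.

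Further down, the peak on 2R from 18639054 to 18639461 (signal 2170.1) was 10 bp from CG30122 and 277 bp from tRNA:Trp-CCA-2-2. Ribosomal protein genes came 6 times among the 25 peaks: RpS21 with CG3104 (signal 1946.2), RpL34b with CG8132 (1680.4), RpS27 with Nup37 and sisRNA:CR46364 (1514.9), RpL32 with CG7943 (1443.3), RpS28b (1195.5) and RpS2 (1168.0). The proteasome lid gene Rpn6 shared a peak with ave (1676.1). The snoRNA host gene Uhg4 shared one with snoRNA:Psi28S-2949 and snoRNA:Or-aca5 (1310.3). The remaining promoter peaks lay at CG5180 (1956.9), trc with CG32221 (1906.8), MESK2 with TAF1C-like (1595.5), Daxx with Sec61alpha and lncRNA:CR45463 (1232.7), Sox14 (1215.3), Pym (1214.7), Sumo (1207.7), jagn (1186.5) and Capr (1153.9). The exception was the peak on 3L from 14004033 to 14004354 (1882.8), in an intron, 2069 bp from the nearest start site, that of upSET. Opbp itself (FBgn0050443, 2R from 6653217 to 6655267) had no conservative summit within 500 bp of its start, and the nearest was 2668 bp away with a signal of 96.9. Optix (FBgn0025360) had none either, and its nearest summit was 10436 bp away.

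Bound start sites belonged to divergent gene pairs far more often than others. Of 4626 protein-coding start site clusters within 500 bp of a summit, 57.5% (exact 95% interval 56.0% to 58.9%) had a protein-coding gene leaving in the opposite direction within 1000 bp upstream, against 22.1% of the 13959 other clusters. The odds ratio was 4.77 (95% interval 4.44 to 5.12, two-sided Fisher's exact test with a p too small for the software to compute). The interval and the test treat the clusters as independent, although 1 summit can bind both members of a pair. The interval is therefore too narrow and the p too small. In the replicates' own lists the share was 59.1% ± 1.18 (SD, n = 3). A summit between 2 start sites can count for both: promoter summits moved to random clusters, each at its own distance, gave a mean odds ratio of 1.88, with 2.07 the highest of 200 placements (one-sided permutation p = 0.005, the smallest they can give). With each summit given to its nearest cluster alone, which counts the partner of a bound start site as not bound, the odds ratio was 2.25 (2.08 to 2.44), and 1.31 (1.20 to 1.42) when bound and other clusters were both limited to those near a ranked peak in all 3 replicates.

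In all, 4444 of 18277 annotated genes, 24.3%, had a start site within 500 bp of a conservative summit, among them 4007 of 13968 protein-coding genes, 28.7%. Of 29 gene lists fixed before the data were examined, 12 were bound more often than other genes and 4 less often, past an adjusted p of 0.05 (two-sided Fisher's exact tests, Benjamini-Hochberg adjustment over the 29 lists). Each of the 16 differed in the same direction in the lists of all 3 replicates. No control precipitation was analysed here, and a gene called bound is one with a nearby summit. Signal that very active genes can give without the tagged protein was therefore not told apart from binding in any of these lists.

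Genes of several parts of the protein synthesis machinery were bound more often than other genes. Of 86 cytosolic ribosomal protein genes, 57 were bound, 66.3% (95% interval 55.3% to 76.1%) against 28.5% of other protein-coding genes (odds ratio 4.94, adjusted exact p = 5.0e-12). The replicates' own lists held 56.6% ± 0.671 of them (SD, n = 3). RpS21, RpL34b, RpS27 and RpL32, named above, had the highest signals. Of 51 translation initiation and elongation factors 29 were bound, 56.9% (odds ratio 3.29, adjusted exact p = 8.8e-05), led by the eIF3 subunit genes eIF3h, eIF3f1 (signal 858.2) and eIF3a (749.2) and by eIF1 (1083.9). Of 34 ribosome biogenesis factors 23 were bound, 67.6% (odds ratio 5.22, adjusted exact p = 9.7e-06), with RIOK2 (524.6), Mpp6 (343.1), Rrp42 (334.7) and Rrp46 (333.4) the strongest. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 12 of 18 genes bound (odds ratio 4.98, adjusted exact p = 0.0018), led by TrpRS (681.1), GlnRS (524.6, at the same peak as RIOK2), AspRS (267.8) and GluProRS (265.5). Mitochondrial ribosomal protein genes were bound in 38 of 73 cases, 52.1% (odds ratio 2.72, adjusted exact p = 1.0e-04), and mRpL4 (770.5), mRpL17 (602.6), mRpL33 (506.3) and mRpL30 (451.8) had the strongest peaks. With regions shared by the other replicates, the odds ratio of this list was 1.19 without replicate 1, 1.87 without replicate 2 and 1.49 without replicate 3, and it passed only without replicate 2; that of the cytosolic synthetases was 1.72, 2.75 and 2.41 and passed in none of the 3.

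tRNA genes were the list with the smallest adjusted p. Of 295, 201 were bound, 68.1% (95% interval 62.5% to 73.4%) against 23.6% of all other genes (odds ratio 6.92, adjusted exact p = 3.2e-56), and 55.9% ± 14.8 in the replicates' own lists (SD, n = 3). These genes lie in clusters, and 167 conservative peaks accounted for the 201. The interval and the test treat the genes as independent, so the interval is too narrow and the p too small. At 25 of those peaks a protein-coding gene also started within 500 bp. The strongest of these peaks was counted for tRNA:Trp-CCA-2-2, but its summit lay 277 bp from that gene and 10 bp from the start of CG30122. It may therefore belong to CG30122. The next were at tRNA:Gly-TCC-1-2 (553.8), tRNA:Glu-CTC-2-3 (539.4) and tRNA:Ser-TGA-1-1 (509.3). The median signal was 188.2 at tRNA gene peaks and 125.1 at the others. The odds ratio was 4.51 without replicate 1, 7.94 without replicate 2 and 4.17 without replicate 3, past the threshold each time.

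Protein turnover, splicing and cell division genes were also bound more often. The proteasome had 22 of 32 genes bound, 68.8% (odds ratio 5.49, adjusted exact p = 9.7e-06), with Rpn6 followed by Prosalpha7 (801.0), Rpn10 (710.4) and Rpn5 (591.3). The spliceosome had 23 of 33, 69.7% (odds ratio 5.74, adjusted exact p = 5.1e-06), with SmD3 (671.1), SmE (615.0), Sf3a1 (558.4) and U2A (345.8). The chaperonin CCT, which folds actin and tubulin, had 7 of 8 (odds ratio 17.4, 95% interval 2.24 to 786, adjusted exact p = 0.0018), with CCT1 (254.6), CCT7 (241.1), CCT2 (167.7) and CCT8 (158.6). DNA replication genes were bound in 22 of 38 cases (odds ratio 3.43, adjusted exact p = 4.8e-04), with geminin (803.9), PolA1 (462.0), Orc5 (307.0) and PCNA (246.0). Cell cycle regulators were bound in 20 of 34 (odds ratio 3.56, adjusted exact p = 8.4e-04), with ida, Bub1 (498.1), BubR1 (474.2) and CycB (455.9). Of 20 chromatin architectural protein genes 12 were bound (odds ratio 3.74, adjusted exact p = 0.0082), with Dref (1073.5) and BEAF-32 (482.2), whose products bind the DNA replication-related element (DRE), and pita (357.0) and dwg (226.3). Against a background of genes near a ranked peak in all 3 replicates, 6 of these 12 lists no longer passed: the mitochondrial ribosomal proteins (odds ratio 1.5), the cytosolic aminoacyl-tRNA synthetases (2.40), CCT (8.38), DNA replication (2.40), cell cycle regulators (2.40) and architectural proteins (2.64). With regions in all 3 replicate lists, without replicate 1, and without replicate 3, 6 of the 12 did not pass: the same ones except that the spliceosome stood in place of the cell cycle regulators. The odds ratio of the spliceosome was then 2.63 without replicate 1 and 2.01 without replicate 3, that of CCT 3.62 and 3.76, that of DNA replication 1.61 and 1.95, and that of the architectural proteins 2.59 and 2.69. These 4 lists passed without replicate 2. The cell cycle regulators passed without any 1 replicate, with odds ratios of 6.83, 4.34 and 4.97.

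Chemosensory receptor and cuticular protein genes were bound less often than other genes. Of 179 chemosensory receptor genes 6 were bound, 3.35% (odds ratio 0.0849, adjusted exact p = 2.1e-17), with Gr97a (157.3), Ir31a (124.1), Ir60e (104.8) and Ir76a (104.5) the strongest. The odds ratio of this list was 0.0334 without replicate 1, 0.0726 without replicate 2 and 0.0346 without replicate 3. Of 89 cuticular protein genes 1 was bound, Cpr73D (105.2; adjusted exact p = 1.8e-11). None of the 111 histone genes (adjusted exact p = 5.9e-16) and none of the 96 genes for 5S ribosomal RNA (adjusted exact p = 1.8e-11) was bound. Both of these families lie in arrays of near-identical copies, where reads cannot be placed uniquely, and 4 of the histone genes and 1 of the 5S genes were near a ranked peak in all 3 replicates, so their count of 0 is not a measure of binding. The histone genes no longer passed against the background of genes near a ranked peak in all 3 replicates. The 13 lists that did not pass included the Hox and segmentation factors (9 of 34 bound), the eye determination network (5 of 11), neuronal genes (2 of 23), muscle genes (3 of 22), chorion and vitelline membrane genes (2 of 17), heat shock genes (7 of 19), small nuclear RNA genes (11 of 32), the respiratory chain (32 of 86), RNA polymerase subunits (14 of 30), the vacuolar ATPase (11 of 33), mitochondrial protein import (6 of 11), mitochondrial aminoacyl-tRNA synthetases (3 of 15) and glycolytic enzymes (7 of 12).

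**Figure D3:**
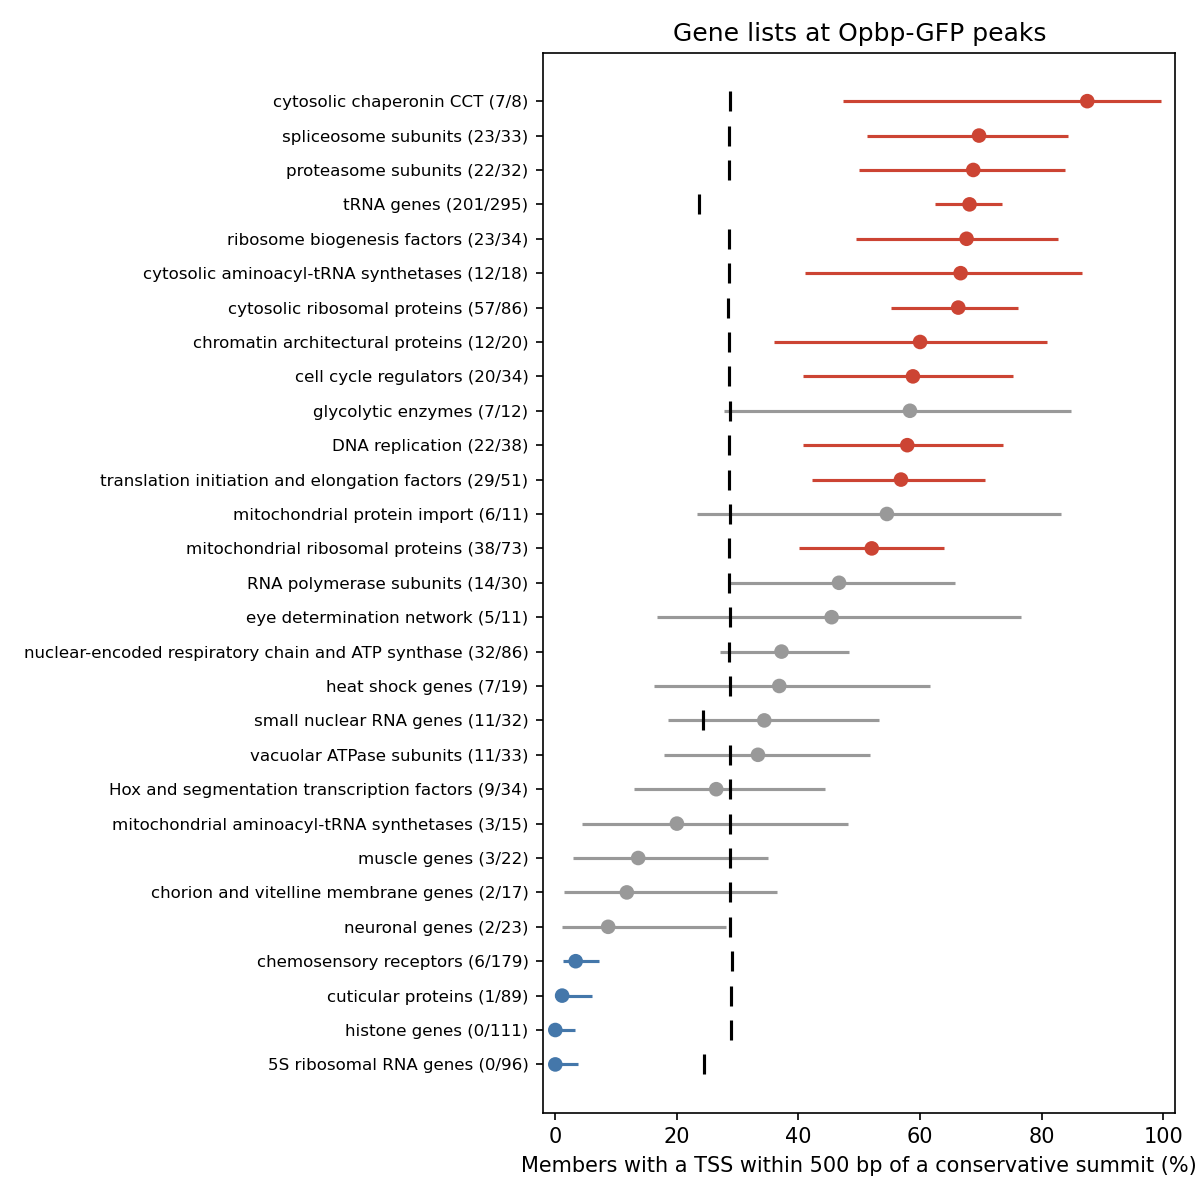
Percent of the members of each gene list with a start site within 500 bp of a conservative summit, with exact 95% Clopper-Pearson intervals; vertical ticks give the percent among other genes, and red, blue and grey mark lists bound more often, less often or not past an adjusted p of 0.05. The 12 red lists are led by CCT, with 7 of 8 genes bound.

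The DNA under the summits was searched for shared sequence on arms 2L, 2R and 4, and what was found was tested on 3L, 3R and X. The 8-mer with the smallest p against unbound promoters was ATCGATAG. It was present within 50 bp of 14.8% of the summits and in 0.609% of control windows (one-sided Fisher's exact test, adjusted exact p = 2.7e-180). It overlaps the DRE, TATCGATA. A position weight matrix grown from it had the core ATCGATA, and on the held-out arms 558 of 2630 peaks had a match, 21.2% (95% interval 19.7% to 22.8%) against 1.19% of controls (odds ratio 22.4, 95% interval 19.3 to 26.0). In the replicates' own lists the share was 26.2% ± 4.46 (SD, n = 3). Matches became more frequent with peak signal, from 3.22% in the weakest decile of the conservative peaks to 44.1% in decile 9. The share then levelled off, at 45.2% in decile 10, the strongest. The exact DRE went from 33.3% in decile 9 to 29.6% in the strongest, and 9 of the 25 strongest peaks had a DRE-like match. In the weakest decile 50.3% of the peaks overlapped a stronger one. Without such peaks, the share of matches was 4.14% in the weakest decile, 45.5% in decile 9 and 44.4% in the strongest.

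Among 9 known core promoter sites counted at all conservative summits, the DRE had the highest odds ratio: it was present at 15.6% of the peaks and in 0.786% of control windows (odds ratio 23.3, 95% interval 20.3 to 26.7). Motif 1, another element of housekeeping promoters, was present at 3.84% against 1.14% (odds ratio 3.46, adjusted exact p = 3.1e-34). The core promoter E-box (8.87% against 5.64%), Motif 6 (2.00% against 1.36%) and the GAGA repeat (2.53% against 2.02%) were also more frequent, with adjusted exact p of 8.7e-16, 0.0015 and 0.033 (two-sided Fisher's exact tests, adjusted over the 9 sites). In the replicates' own lists the GAGA repeat was at 2.03% ± 0.267 (SD, n = 3), which did not exceed the control share by more than the spread. The TATA box (8.50% against 16.1%, adjusted exact p = 1.7e-44), the initiator (19.8% against 29.2%, adjusted exact p = 1.3e-41) and the TCT element of ribosomal protein genes (7.31% against 9.28%, adjusted exact p = 1.6e-05) were less frequent. The site of the early activator Zelda did not differ (0.482% against 0.570%, adjusted exact p = 0.52).

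**Figure D4:**
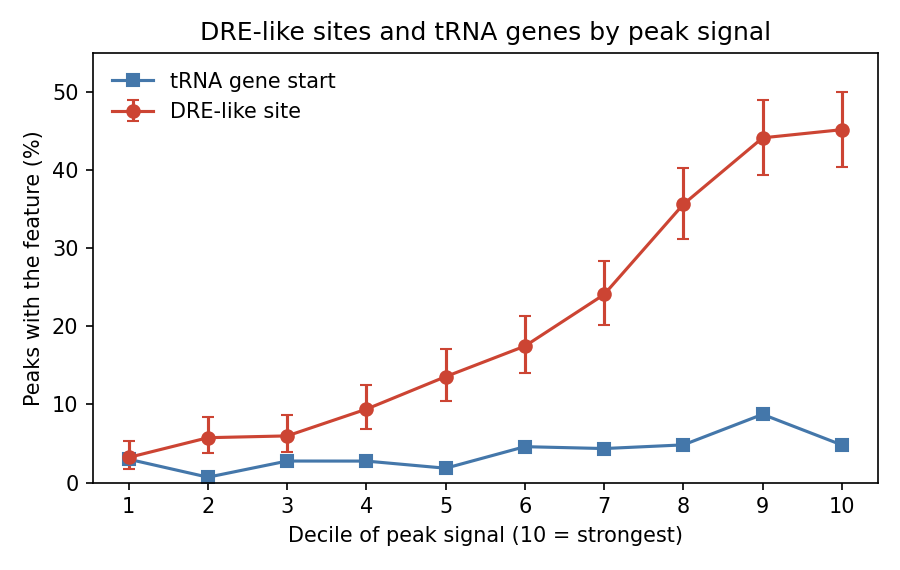
Percent of conservative peaks with a DRE-like match within 50 bp of the summit (red, with exact 95% Clopper-Pearson intervals) and with a tRNA gene start within 500 bp (blue), by decile of peak signal. The DRE-like share goes from 3.22% in the weakest decile to 44.1% in decile 9 and 45.2% in the strongest.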

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

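In this part, the test of DRE-like sites in windows of 300 bp and the placement of summits at random clusters were chosen after the results were seen, and the other settings for divergent pairs (the nearest cluster alone, and clusters near a ranked peak) were added after seeing the data. Outside the major arms, which the comparisons above used, the conservative list held 5 peaks, all on unplaced pieces of X; this is signal in data that no comparison covered. With 1 group of 3 replicates, a sample far from the others and a difference between groups were not tested.

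Divergent gene pairs were common among the bound start sites. If a pair of nearby start sites merely gave 1 summit 2 chances to count, the odds ratio would reach 1 with each summit given to its nearest cluster; it was 2.25 (2.08 to 2.44), although that rule itself lowers the value. If the other start sites differed only by holding silent genes, it would reach 1 among clusters near a ranked peak in all 3 replicates. It was 3.11 (2.87 to 3.37), with an interval that also treats the clusters as independent. That background cannot decide the point, since a ranked peak does not mark an active promoter. The ranked lists of replicates 1, 2 and 3 held 106686, 109408 and 87469 peaks. Of 179 chemosensory receptor genes, 47 were near a ranked peak in all 3. With pair geometry and this background together, summits placed at random among the clusters near a ranked peak gave a mean of 1.96. The highest of 200 placements was 2.29, below the observed 3.11. Differences in promoter activity stay open. The labels give no second group, so no biological explanation was tested.

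DRE-like sites under the peaks may only mark the class of housekeeping promoters, for which the DRE is known. The test written beforehand, the median distance of the site from the summit minus that from the start site, gave -17.0 bp (-18.0 to -13), but sites were searched within 50 bp of the summit, which bounds the first distance, so it decides nothing. In windows of 300 bp around either point, the share of matches within 25 bp was higher around summits than around start sites by 10.6 percentage points (7.31 to 13.9). At these promoter summits the sites lay closer to the peak than to the annotated start site. The summits included those of the discovery arms, where the matrix was grown from windows within 50 bp of them. That favours closeness to the summit, so the promoter class is not excluded. The DRE-like sites are not the peaks' sole sequence feature: with them masked, 182 of 311 other 8-mers found on the discovery arms also passed on the held-out arms. Several of these overlap as shifts of the same word, so 182 is not a count of separate features. Peaks at tRNA genes were included in the search, and the 8-mers were not told apart by class of gene. The matrix grown from the first of them matched 3.27% of the held-out peaks and 1.17% of controls. Whether Opbp itself, another DRE-binding protein or the openness of these promoters gives the signal stays open, since no control precipitation was analysed here.

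tRNA genes were bound often, and the DRE-like site is not how. Only 0.599% of the 167 peaks at tRNA genes had one (95% interval 0.0152% to 3.29%), against 21.2% of other peaks. Reads shared between identical copies stay open as a cause. Of 57 tRNA genes with a sequence found once in the annotation, 50.9% were bound (37.3% to 64.4%), against 24.3% of all genes. That share cannot decide it, since a summit within 500 bp may belong to a neighbouring gene of the same cluster. Near-identical copies may share reads as well. Copies with the same sequence were bound in 72.3% of cases, so shared reads may add to the count. Very active genes can also give signal without the tagged protein, which no value here tests, and no biological explanation besides the DRE-like site was tested. The matrix grown after masking that site matched 1.80% of tRNA gene peaks and 3.30% of the others, a difference that was not tested.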

How the results depend on the processing

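The promoter share, the replicate overlap, the divergent share and the motif share kept their direction and stayed past their tests under every alternative run, those added after seeing the data included. The promoter share ranged from 74.4% with the largest thresholded list to 94.1% with regions in all 3 replicate lists, the mean replicate overlap from 54.3% to 75%, the divergent odds ratio from 1.31 to 5.10, and the motif share from 14.7% to 28.9%. Each setting grew its own matrix, so the motif shares are not of 1 matrix. The lowest share came with flanks of the same peaks as control, where the matrix read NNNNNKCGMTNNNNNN and lacked the core ATCGATA. The matrices of the other settings held that core. The number of gene lists past the threshold, 16, ranged from 9 to 19. It was 9 against a background of genes near a ranked peak in all 3 replicates, where fewer genes were compared: 8 of the 16 and the neuronal genes, which were bound less often, with 5S genes left untested. It was 10, all among the 16, with regions in all 3 replicate lists, which are fewer than the conservative peaks. Leaving out a replicate gave between 10 (without replicate 1 or replicate 3) and 16 (without replicate 2, 15 of them among the main 16) lists. The signal agreement moved in 1 case: leaving out a replicate gave a mean rho between 0.602 (without replicate 1) and 0.841 (without replicate 2), and the cause was not tested. Among the single lists' odds ratios, 145 results stayed on their side of the threshold under the alternatives and 29 kept their direction but no longer passed; no odds ratio changed direction. Cytosolic ribosomal proteins, translation factors, proteasome subunits, ribosome biogenesis factors, tRNA genes, cuticular proteins and chemosensory receptors passed under all 11 alternatives. Without read depth, the limit it sets on weaker peaks is unknown.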

Other observations

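The test of the element below was chosen after the strongest peaks of all arms had been looked at, so the arms used to test it are not fully independent. Many of the strongest peaks held a sequence other than the DRE. In the 25 strongest peaks of 2L, 2R and 4, the 8-mer CCAACTTC was present at 28%, against 0.236% of the other conservative peaks there (one-sided Fisher's exact test, adjusted p = 5.3e-07), and the matrix grown from it read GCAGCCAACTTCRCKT. A strict score was then set so that 50 positions of 3L, 3R and X passed it. Of the 25 strongest peaks on those arms 9 had such a match, 36.0% (exact 95% interval 18% to 57.5%), and 5 of the 2605 others, 0.192% (odds ratio 283, 95% interval 75.8 to 1203, Fisher's exact test over peaks). Because these peaks had been looked at before, the odds ratio describes them and does not decide whether the element marks strong binding. Among the 25 strongest peaks of the whole list, 12 were on 3L, 3R or X and 7 of these had a match, among them those at UQCR-C1 and CycC, ida and trc; the other 6 with a match were on arms from which the matrix was grown. Of the 25 strongest peaks of the whole list, 13 had a match, 9 had a DRE-like site, 4 had both and 7 had neither. The strongest peak, at CG3764, had neither. On 3L, 3R and X, 14 conservative peaks had a match, and 13 of them were in the strongest decile of the list.

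Of the 50 highest-scoring positions on 3L, 3R and X, 14 lay within 100 bp of a summit. These were 13 of the 20 positions within 500 bp of a start site, 65%, and 1 of the 30 farther away. The median distance from a bound position to its summit was 8.5 bp. Of the exact DRE sites on 2L, 2R, 3L, 3R, 4 and X, 887 of 1565 within 500 bp of a start site were near a summit, 56.7% (95% interval 54.2% to 59.1%), and 40 of 2454 farther away, 1.63% (1.17% to 2.21%).

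With the DRE-like sites masked and 8-mers ranked by p, CATCTCTA came first on the discovery arms (2.96% of peaks against 0.215% of controls). It was present at 2.89% of the peaks on the held-out arms, against 0.338%. It was followed by AGAGATGG, by GGTCACAC, which is part of Motif 1, and by GGGTTCGA (1.74% against 0.128% on the discovery arms).

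Around the Opbp gene, a window of 40 kb held 56, 48 and 48 ranked peaks in replicates 1, 2 and 3, against medians of 37, 37 and 30 over windows of that size on 2R. These counts were at percentiles 96.7, 93.9 and 98.0 of the windows. Ranked peaks include weak ones below the authors' threshold, so the counts do not measure binding at Opbp. The cause of the higher counts was not tested.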
